A study of Rattus norvegicus with 12 samples.

How the data were processed

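Gene expression was measured in lung tissue of male Sprague Dawley rats weighing 250 to 350 g, on 12 Affymetrix arrays hybridised with labelled RNA made from 6 ug of total RNA each. The labels put 3 arrays in each of 4 groups. These are sham, BD (brain death, brought about by inflating a balloon catheter outside the dura), SEW (an intravenous injection of SEW-2871 at 0.1 mg/kg) and BD/SEW (the same dose given 15 min after brain death). The labels do not number the animals and do not say whether the SEW animals had the sham operation, so the p-values measure the spread between samples.

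The deposited values are log2 probe set values with 2 decimals. RMA, MAS5 and affy are named in the submitters' processing notes without a version or a role for each. The values of the 12 arrays differed by at most 0.22 log2 units at any rank, as they do after quantile normalization between arrays. Raw array files were not used here. The number of arrays limits the precision, and no depth applies.

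The deposited table holds 31042 probe sets and 0 control probe sets, so the ratio of probe sets at the ends of a transcript was not analysed here. Gene symbols were attached from the annotation table of the array, which gave 1 symbol to 20826 probe sets, several to 436 and none to 9780. Of the probe sets with 1 symbol, 20760 matched a gene in the RefSeq gene table of assembly GRCr8, which was used for names only. Where a gene had several probe sets (4525 genes), the probe set with the highest mean over all arrays was used, which left 14217 genes. Genes of multigene families, such as the mast cell proteases Mcpt8 and Mcpt9 or the Oas, Ifit and Mx genes, can share probes, and their values are less certain for that reason.

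Genes were compared with limma 3.58.1 in R 4.3.3. A mean was fitted per group over all 12 arrays, the variances were moderated with a mean trend, and p-values were adjusted by the Benjamini-Hochberg method over the 14217 genes. A gene was called at an adjusted p under 0.05, and the tests were two-sided. The 6 comparisons were BD against sham, SEW against sham, BD/SEW against BD, BD/SEW against SEW, BD/SEW against sham, and the interaction, which is the brain-death effect with the agonist less the brain-death effect without it.

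A set of 29 gene lists was written before the data were examined. They cover inflammatory and stress pathways, endothelial and alveolar functions, the receptor's own pathway and markers of cell types a lung sample can hold. The lists were tested with camera at a preset correlation of 0.01, adjusted over 174 tests, and also with an estimated correlation and with fry. For each list the calls over all genes and the calls adjusted over the list alone were counted. With the estimated correlation no list passed in any comparison, the smallest adjusted p being 0.14. With fry 19 of the 174 tests passed. These were 3 in BD against sham, 4 in SEW against sham, 0 in BD/SEW against BD and 4 in BD/SEW against SEW. A further 5 were in BD/SEW against sham and 3 in the interaction. A further 4 lists, of basophil, mast cell, platelet and adipose markers, were written after the data had been seen.

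The rule for named genes was fixed before the data were examined. For each comparison it takes up to 10 called genes with the largest rise and 10 with the largest fall, without overlap between the arrays of the groups (not asked of the interaction) and with a group mean above the 25th percentile of all genes. It adds up to 4 called members of each list, and S1pr1 in every comparison. With fewer than 10 calls it takes all called genes and the 5 genes with the smallest p. Members of a list outside this rule are named after their values were seen.

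The gene test was tested on simulated data with the real means and spreads, in which 200 of the 14217 genes were changed in each of 10 draws. For BD against sham it found 49.9% of genes changed 1.5-fold, 88.5% of those changed 2-fold and 98.8% of those changed 4-fold, with a mean of 6.9 false calls per draw. For the interaction it found 17.2%, 65.5% and 95.5%, with 6.7 false calls per draw. For BD against sham, the list test found 10 of 10 lists shifted by 0.5 and called 1 of 10 unshifted lists, at an unadjusted p. These lists held random genes with independent noise, so this does not test the preset correlation on genes that vary together. In the real lists the estimated correlation ran from -0.025 (sphingosine 1-phosphate) to 0.89 (cardiac).

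The shared brain-death response was set beside 100 simulations without an interaction, and the effect of the agonist on brain-death genes beside 100 simulations without an agonist effect. Noise in these simulations was drawn independently for each gene. In a version chosen after the first had been seen, each simulated effect was multiplied by the share of its variance that is not error, since the first gave many more calls than the data.

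Alternatives were a fit on the compared arrays only, the replicate number as a block, variance moderation without the trend or with robust estimation, array weights, quantile normalization, median centring, filters on dim genes, the mean of a gene's probe sets, every probe set on its own, a fold threshold of 1.5, an adjusted p under 0.01, and each array left out in turn. Chosen after seeing the data were a fit with the cardiac marker mean of each array as a covariate and a fit without BD replicate 2, SEW replicate 2 and sham replicate 3. No array was left out otherwise. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and array weights and robust fits used statmod 1.5.0.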

Results

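The data are log2 expression values of 14217 genes in rat lung, with 3 arrays in each of the sham, BD, SEW and BD/SEW groups. SEW-2871 is an agonist of S1P1, the receptor for sphingosine 1-phosphate that S1pr1 encodes and that endothelial cells and lymphocytes carry. The comparisons ask what brain death changes in the lung, what the agonist changes without brain death, and whether the agonist alters the response to brain death. S1pr1 itself was 13.34 ± 0.04 in sham, 13.27 ± 0.06 in BD, 13.28 ± 0.12 in SEW and 13.33 ± 0.04 in BD/SEW (log2 mean ± SD, n = 3), and it passed in no comparison. Array medians lay between 7.34 and 7.41, and the number of arrays limits the precision.

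Some arrays held transcripts of other tissues. The mean of the 18 measured cardiac muscle markers was 10.39, 9.97 and 9.39 in the sham arrays and 11.38 in BD replicate 2, against 5.74 to 7.99 in the other 8 arrays. The mean of 12 adipose markers, a list chosen after seeing the data, was 10, 9.24 and 9.03 in the sham arrays and 9.55 in BD replicate 2, against 6.53 to 7.53 in the others. Heat shock and chaperone genes had a mean of 12.34 in SEW replicate 2 and of 10.46 to 10.73 in the other 11 arrays. Sham replicate 3 and SEW replicate 2 had the lowest array weights, 0.25 and 0.32.

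**Figure D1:**
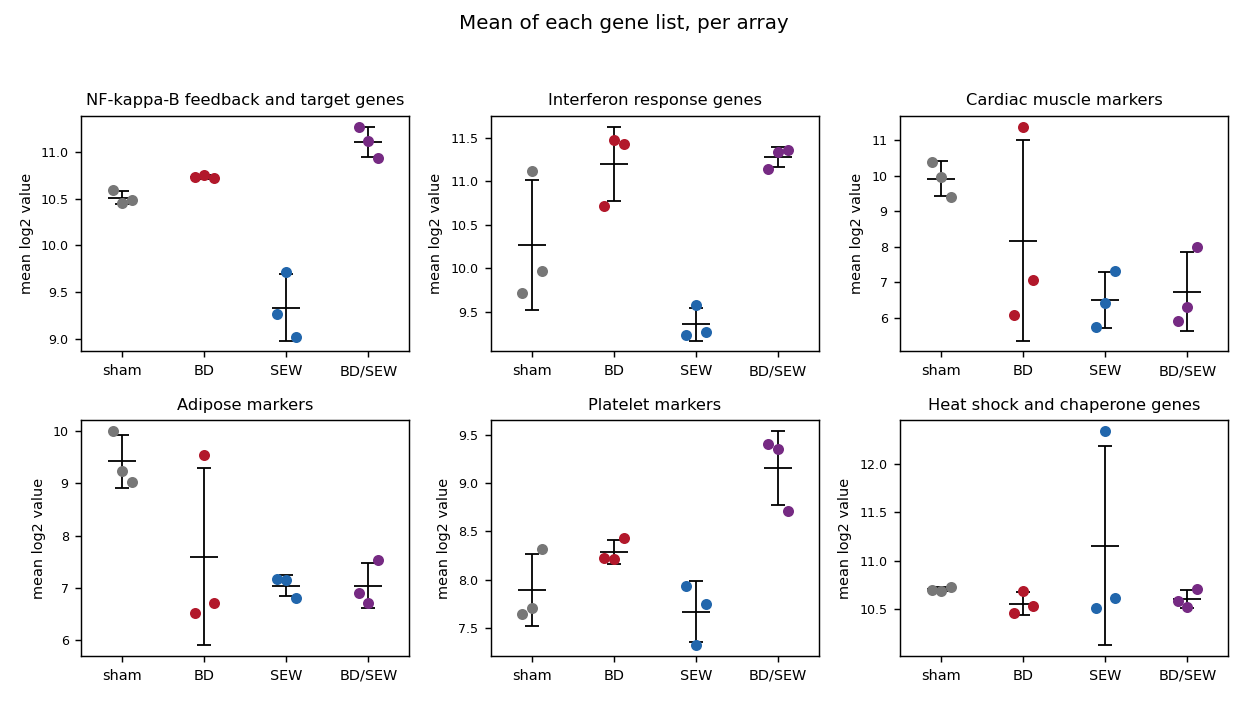
Mean log2 value of 6 gene lists (y axis) in each array of the 4 groups (x axis); points are arrays and bars give the mean ± SD of 3 arrays. The NF-kappa-B list lies between 9.02 and 9.72 in the SEW arrays and between 10.46 and 11.27 in the others, and the cardiac list reaches 11.38 in BD replicate 2.

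BD against sham asks what brain death does to the lung. Mycn, a transcription factor of the MYC family, rose by 2.94 ± 0.32 (log2 fold change ± SE, n = 3 per group; adjusted p = 0.0037) and Tnfsf10, which encodes the death ligand TRAIL, by 2.63 ± 0.18 (adjusted p = 0.00012). Irf1, an interferon regulatory factor, rose by 1.37 ± 0.17, and Ripk2, a kinase of the NOD pathway, by 1.84 ± 0.29 (called in 3 of the 6 fits with a compared array left out). Rgs1, a regulator of G protein signalling, fell by 2.27 ± 0.2 (adjusted p = 0.0012), and Ddit4, an inhibitor of mTORC1 signalling, fell by 1.89 ± 0.24 (adjusted p = 0.0043). In BD 30 genes rose and 54 fell against sham, and 9 of the raised and 26 of the lowered changed at least 2-fold. The cardiac mean was 9.39 to 10.39 in the sham arrays and 6.08 and 7.06 in BD replicates 1 and 3. Tissue make-up may thus be a source of these differences beside brain death. In 2231 genes (15.7%) the BD and sham arrays did not overlap, where chance gives 10%. The count of 84 was 37 without sham replicate 1, 49 without sham replicate 2, 26 without BD replicate 1, 227 without BD replicate 2 and 37 without BD replicate 3. It was 499 without BD replicate 2, SEW replicate 2 and sham replicate 3 together and 28 with the cardiac covariate (both chosen after seeing the data), 13 with the compared arrays only, 383 with array weights, 134 over every probe set and 22 at an adjusted p under 0.01.

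Among the 18 cyclic AMP and catecholamine response genes, 1 rose, 2 fell and 15 did not pass, while 2 rose and 11 fell adjusted over the list alone. Crem, a cyclic AMP responsive transcription factor, fell by 1.52 ± 0.29 (adjusted p = 0.04), and Adrb1, the beta-1 adrenergic receptor, rose by 1.02 ± 0.19 (adjusted p = 0.04). Each was called in 1 of the 6 fits with a compared array left out, and neither with the cardiac covariate, nor was Crem with the replicate number as a block. Sik1, a kinase that cyclic AMP induces, fell by 1.11 ± 0.13 (adjusted p = 0.0037) and was called in 6 of these 6 fits. The list median was -0.545 (adjusted p = 9.9e-06 with the preset correlation, adjusted p = 0.14 with an estimated correlation, adjusted p = 0.012 by fry). Of 18 glucocorticoid response genes, 2 fell, Ddit4 and the phosphatase gene Dusp1 (-0.67 ± 0.1, called in 2 of the 6 fits), and 1 rose and 7 fell adjusted over the list alone (median -0.248, adjusted p = 1.6e-05, adjusted p = 0.28 with an estimated correlation). All 22 interferon response genes were higher in BD than in sham, but 0 passed over all genes and 4 were higher adjusted over the list alone. Their median was 0.915 (adjusted p = 2.1e-09, adjusted p = 0.44 with an estimated correlation, adjusted p = 0.14 by fry), and the antiviral gene Rsad2 differed by 2.22 ± 0.63 without passing (adjusted p = 0.17). The list mean was 11.11 in sham replicate 2, against 9.71 and 9.97 in the other sham arrays. The cardiac list had a median of -1.85 in this comparison with 0 members called (adjusted p = 0.00016, adjusted p = 0.62 with an estimated correlation).

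**Figure D2:**
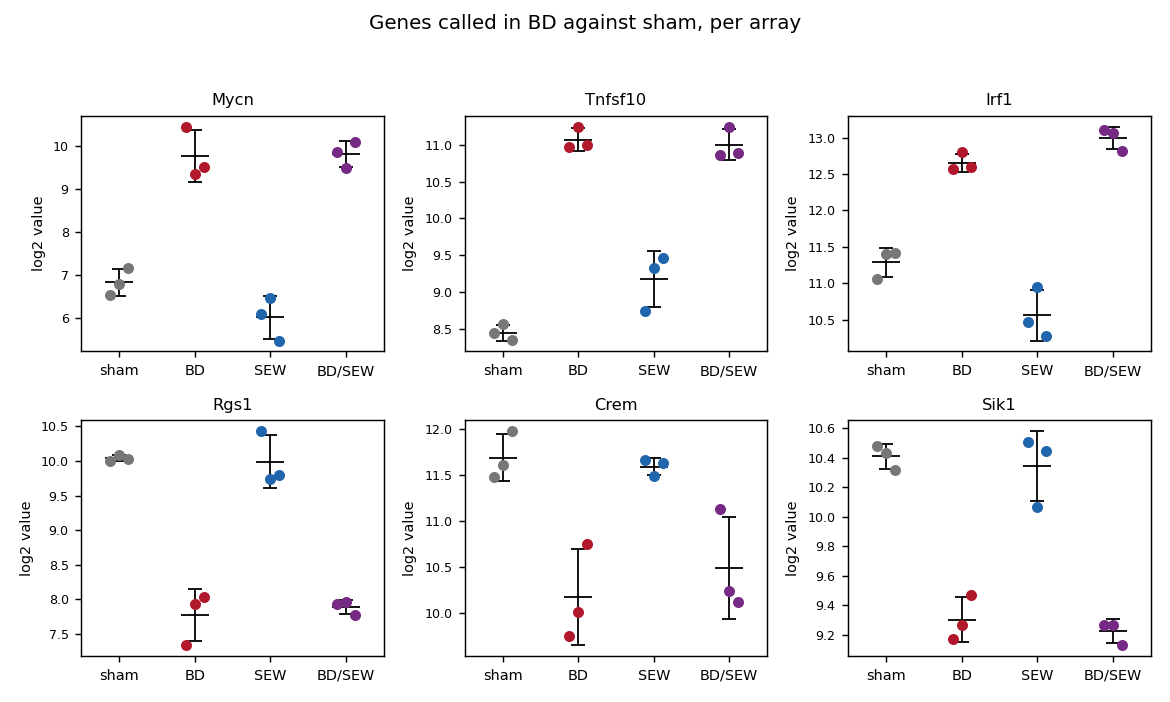
Log2 value (y axis) of 6 genes called in BD against sham, in each array of the 4 groups (x axis); points are arrays and bars give the mean ± SD of 3 arrays. Mycn averages 9.77 in BD and 9.81 in BD/SEW, against 6.83 in sham and 6.02 in SEW.

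SEW against sham asks what the agonist does in animals without brain death. The labels do not say whether the SEW animals had the sham operation, so the differences may come from the operation or the agonist. Heart and fat tissue in the sham pieces is a further possible source, which this design cannot separate from them. The cardiac mean was 9.39 to 10.39 in the sham arrays and 5.74 to 7.31 in the SEW arrays. The adipose mean was 9.03 to 10 and 6.81 to 7.17. Sele (E-selectin), an adhesion molecule of activated endothelium, fell by 4.69 ± 0.48 (n = 3 per group; adjusted p = 0.00097), Selp (P-selectin) fell by 3.47 ± 0.47 (adjusted p = 0.0039) and Vcam1 fell by 1.36 ± 0.15 (adjusted p = 0.0015). They were the 3 called members of 18 endothelial activation and coagulation genes, of which 15 did not pass, Icam1 among them (-0.64 ± 0.18, adjusted p = 0.058), and 8 were higher. Adjusted over the list alone 1 rose and 4 fell (median -0.23, adjusted p = 0.031, adjusted p = 0.46 with an estimated correlation). The chemokine genes Cxcl10 and Cxcl11 fell by 4.36 ± 0.7 and fell by 4.4 ± 0.67. Sele (5.03), Cxcl10 (5.43), Cxcl11 (5.2) and Il6 (5.47) averaged below the lower quartile of the arrays (5.56 to 5.66) in SEW, where signal over background was not measured, so the size of their changes against SEW is uncertain here and below. Klf2, a transcription factor that blood flow induces in endothelium, rose by 1.48 ± 0.19 (adjusted p = 0.0035), and Hey1, a target of Notch signalling, rose by 1.88 ± 0.3 (adjusted p = 0.0089). Spns2, which exports sphingosine 1-phosphate from endothelial cells, rose by 1.18 ± 0.21. In all, 484 genes rose and 346 fell, of which 29 and 143 changed at least 2-fold. With the compared arrays only 47 rose and 210 fell, and with the cardiac covariate 0 rose and 24 fell, so no rise named here, Klf2, Hey1, Spns2, Sox18 and Cldn5 among them, passed with it. Of 14217 genes, 27.1% did not overlap between the groups, where chance gives 10%. The count of 830 was 426, 401 and 321 without sham replicate 1, 2 or 3, 547 without SEW replicate 1 and 502 without SEW replicate 2. It was 257 with the compared arrays only, 1556 with array weights, 512 at 1.5-fold or more, 109 at an adjusted p under 0.01 and 24 with the cardiac covariate (chosen after seeing the data).

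Of 19 genes of NF-kappa-B feedback and targets, 14 fell and 5 did not pass, and 15 fell adjusted over the list alone. Birc3, an inhibitor of apoptosis, fell by 3.13 ± 0.26 (adjusted p = 0.00033), Tnfaip3, which encodes the A20 inhibitor of NF-kappa-B, fell by 2.38 ± 0.23, and the NF-kappa-B subunit gene Relb fell by 1.74 ± 0.15. The list median was -1.23 (adjusted p = 1.2e-15 with the preset correlation, adjusted p = 0.24 with an estimated correlation, adjusted p = 0.0035 by fry). Of 29 cytokine and chemokine genes, 8 fell and 2 rose, and 12 fell and 2 rose adjusted over the list alone (median -0.347, adjusted p = 3.3e-05, adjusted p = 0.44 with an estimated correlation). Il6 was among those that fell (-3.28 ± 0.74, called in 2 of the 6 fits with a compared array left out), and Il33 among those that rose (0.59 ± 0.13). Of 22 interferon response genes 4 fell, and 12 fell adjusted over the list alone (median -0.91, adjusted p = 9.2e-06, adjusted p = 0.51 with an estimated correlation). Of 20 endothelial identity genes, 4 rose, among them the transcription factor gene Sox18 (1.62 ± 0.28) and the tight junction gene Cldn5 (0.58 ± 0.13, called in 1 of the 6 fits). Adjusted over the list alone, 9 rose and 1 fell (median 0.247, adjusted p = 0.01, adjusted p = 0.44 with an estimated correlation). Of 21 cell cycle genes 3 fell, among them Mki67 (-1.48 ± 0.27), and 1 rose and 6 fell adjusted over the list alone (median -0.323, adjusted p = 7e-05, adjusted p = 0.46 with an estimated correlation). The cardiac list moved with these groups, with a median of -3.83, 1 member called over all genes and 15 adjusted over the list alone (adjusted p = 3.4e-09, adjusted p = 0.46 with an estimated correlation). Of the 12 adipose markers 5 fell (median -2.86).

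The largest falls in SEW against sham also held genes of airway and fat. Bpifa1, a secreted airway protein, fell by 5.37 ± 1.2 (n = 3 per group; adjusted p = 0.029), and the mucin gene Muc5b fell by 2.16 ± 0.55 (adjusted p = 0.045). They were the 2 called members of the 15 airway epithelial markers (median -0.543, adjusted p = 0.0071, adjusted p = 0.62 with an estimated correlation), and 2 fell adjusted over the list alone. Adipoq, the adipocyte hormone adiponectin, fell by 3.65 ± 0.78 and the troponin gene Tnnc1 fell by 3.94 ± 0.93. Bpifa1, Muc5b, Adipoq and Tnnc1 were each called in only 1 of the 6 fits with a compared array left out.

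BD/SEW against BD asks what the agonist changes in animals with brain death. Mcpt8, a protease gene of basophils, rose by 1.73 ± 0.11 (n = 3 per group; adjusted p = 5.7e-05), from 5.63 ± 0.12 in BD to 7.36 ± 0.11 in BD/SEW (log2 mean ± SD). The related gene Mcpt9 rose by 0.82 ± 0.09 (adjusted p = 0.0093), from 4.62 ± 0.1 to 5.44 ± 0.01. The lower quartile of the arrays lay between 5.56 and 5.66, a range that holds Mcpt8 in BD and lies above Mcpt9 in both groups. Signal over background was not measured, so the size of both changes is uncertain. Mcpt9 was called in 2 of the 6 fits with a compared array left out. These were the only calls by limma with all arrays and genes, with 0 genes lowered. At an unadjusted p under 0.05 there were 773 genes, where 711 would be expected by chance, and 12.4% of genes did not overlap between the groups, where chance gives 10%. Next by p were the transporter gene Slc2a6 (1.15 ± 0.18, adjusted p = 0.22), Rab37 (0.79 ± 0.13) and Ldhc (0.61 ± 0.1), which did not pass. The count of 2 was 1 without BD replicate 2, BD replicate 3, BD/SEW replicate 1 or BD/SEW replicate 2, and 5 without BD/SEW replicate 3. It was 8 with the compared arrays only, 5 with array weights, 4 over every probe set and 0 when the dimmer genes were left out before the fit, which removes both genes.

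In BD/SEW against BD no neutrophil marker, cytokine, chemokine or NF-kappa-B gene was called, over all genes or adjusted over the list alone, while 1 of 18 endothelial activation and coagulation genes rose adjusted over the list alone (median 0.0717, adjusted p = 0.56, adjusted p = 0.82 with an estimated correlation). All 15 neutrophil markers were higher in BD/SEW than in BD (median 0.797, adjusted p = 3.8e-07, adjusted p = 0.44 with an estimated correlation). Camp, a neutrophil granule peptide, differed by 1.05 ± 0.46 (n = 3 per group, adjusted p = 0.91 by limma). Of 29 cytokine and chemokine genes 25 were higher (median 0.603, adjusted p = 9.6e-06, adjusted p = 0.44 with an estimated correlation), and of 19 NF-kappa-B genes 18 were higher (median 0.34, adjusted p = 1.3e-07, adjusted p = 0.44 with an estimated correlation). By fry no list passed here, the adjusted p being 0.18 for neutrophil markers, 0.18 for cytokines and chemokines and 0.16 for NF-kappa-B genes. The cardiac list lay in the opposite direction (median -1.51, adjusted p = 2.5e-06, adjusted p = 0.54 with an estimated correlation), and its adjusted p was 0.65 without BD replicate 2.

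BD/SEW against SEW asks what brain death does in animals that also had the agonist, and shares no array with BD against sham. If the SEW animals had no sham operation, this comparison holds the effect of the operation as well. Cxcl10, a chemokine gene that interferon induces, rose by 7.76 ± 0.7 (n = 3 per group; adjusted p = 9.6e-05) and Cxcl11 by 6.28 ± 0.67. Sele rose by 5.98 ± 0.48 (adjusted p = 4.6e-05), Ccl2, which attracts monocytes, by 5.33 ± 0.7, and Il6 by 3.92 ± 0.74. The sizes for Cxcl10, Cxcl11, Sele and Il6 are uncertain, as their SEW values lie below the lower quartile of the arrays. Hey1 fell by 2.3 ± 0.3, and Pdk4, a kinase that restrains glucose oxidation, fell by 2.32 ± 0.41. In all, 676 genes rose and 716 fell, of which 299 and 75 changed at least 2-fold. In 31.8% of genes the arrays did not overlap, where chance gives 10%. The count of 1392 was 790 without BD/SEW replicate 1, 803 without BD/SEW replicate 2 and 885 without BD/SEW replicate 3. It was 2506 with array weights, 2198 over every probe set, 914 at 1.5-fold or more and 629 at an adjusted p under 0.01.

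In BD/SEW against SEW 16 of 19 NF-kappa-B genes rose, and 18 adjusted over the list alone (median 2.09, adjusted p = 1.3e-23 with the preset correlation, adjusted p = 0.14 with an estimated correlation, adjusted p = 0.00036 by fry). Birc3 rose by 3.5 ± 0.26 and Tnfaip3 by 2.88 ± 0.23 (n = 3 per group). Of 22 interferon response genes 17 rose, Rsad2 by 5.14 ± 0.63, and 18 rose adjusted over the list alone (median 2.02, adjusted p = 1.9e-14, adjusted p = 0.44 with an estimated correlation). Of 29 cytokine and chemokine genes 17 rose, Tnf by 3.75 ± 0.34, and 18 rose and 2 fell adjusted over the list alone (median 1.54, adjusted p = 3.7e-11, adjusted p = 0.25 with an estimated correlation). Of 15 neutrophil markers 5 rose, Camp by 3.73 ± 0.46, and 10 rose and 1 fell adjusted over the list alone (median 1.2, adjusted p = 7.5e-07, adjusted p = 0.44 with an estimated correlation). Heat shock genes had a median of -0.583 with 0 members called (adjusted p = 0.036, adjusted p = 0.74 with an estimated correlation), which became an adjusted p of 0.7 without SEW replicate 2. Among 17 genes of sphingosine 1-phosphate receptors and metabolism 2 rose, S1pr2, which encodes another receptor of this lipid, by 1.17 ± 0.15, and 2 rose adjusted over the list alone (median 0.0433, adjusted p = 0.37, adjusted p = 0.59 with an estimated correlation).

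BD/SEW against sham asks how far treated animals with brain death lay from sham animals. Tnfsf10 rose by 2.56 ± 0.18 (n = 3 per group; adjusted p = 0.00017), Mycn by 2.98 ± 0.32 and the cytokine gene Tnf by 2.5 ± 0.34 (adjusted p = 0.0035). The chemokine genes Ccl3 and Ccl4 rose by 2.36 ± 0.4 and 2.46 ± 0.39. Bpifa1 fell by 6.66 ± 1.2 and Thrsp, a lipogenic gene of fat, fell by 3.93 ± 0.9, but with a compared array left out Bpifa1 was called in 3 of the 6 fits and Thrsp in 0, against 6 for Tnfsf10, Mycn and Tnf and 5 for Ccl3 and Ccl4. In all, 242 genes rose and 166 fell, and 25.9% of genes did not overlap, where chance gives 10%. Of 29 cytokine and chemokine genes 8 rose and 1 fell, and 15 rose and 3 fell adjusted over the list alone (median 0.673, adjusted p = 3.5e-06, adjusted p = 0.44 with an estimated correlation). Of 18 cyclic AMP and catecholamine genes 1 rose and 5 fell, among them Sik1 (-1.19 ± 0.13) and Nr4a2 (-0.86 ± 0.11), and 2 rose and 9 fell adjusted over the list alone (median -0.498, adjusted p = 6.6e-05, adjusted p = 0.14 with an estimated correlation). Of 13 alveolar type 1 markers 2 rose, Pdpn (0.5 ± 0.09) and Clic5 (0.59 ± 0.12), each called in 2 of the 6 fits, and 2 adjusted over the list alone (median 0.36, adjusted p = 2.6e-05, adjusted p = 0.44 with an estimated correlation). The median of this list was also 0.287 in BD against sham and 0.27 in SEW against sham, but 0.0667 in BD/SEW against BD. Its shift against sham is thus not particular to BD/SEW. Cardiac markers had a median of -3.32, with 0 of 18 called over all genes and 15 lower adjusted over the list alone (adjusted p = 1.3e-09, adjusted p = 0.46 with an estimated correlation). Of the 12 adipose markers 3 fell (median -2.97). The count of 408 was 141 and 215 without sham replicate 1 or 2, and 120, 91 and 225 without BD/SEW replicate 1, 2 or 3. It was 685 with the compared arrays only, 2685 with array weights, 89 at an adjusted p under 0.01 and, chosen after seeing the data, 12 with the cardiac covariate and 1160 without BD replicate 2, SEW replicate 2 and sham replicate 3.

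The interaction asks whether the brain-death effect differs between animals with and without the agonist. It also holds the effect of the sham operation if the SEW animals had none, which the labels leave unsaid. Sele was 9.73 ± 0.26 in sham, 10.65 ± 0.76 in BD, 5.03 ± 0.99 in SEW and 11.02 ± 0.56 in BD/SEW (log2 mean ± SD, n = 3), an interaction of 5.06 ± 0.68 (SE; adjusted p = 0.0077), whose size is uncertain as the SEW value lies below the lower quartile of the arrays. Birc3 was 11.54 ± 0.18, 11.75 ± 0.23, 8.41 ± 0.68 and 11.92 ± 0.09 in the same order, an interaction of 3.3 ± 0.37 (adjusted p = 0.0032). Klf2 was 10.98 ± 0.36, 10.85 ± 0.2, 12.46 ± 0.26 and 10.71 ± 0.21, an interaction of -1.61 ± 0.27 (adjusted p = 0.021), called in 8 of the 12 fits with an array left out. Csf3, the granulocyte growth factor gene, had an interaction of 3.28 ± 0.45 and the glucose transporter gene Slc2a3 of 2.45 ± 0.29. Part of the Csf3 interaction is a fall in BD against sham, where Csf3 was called. That fall was -2.01 to -1.38 with a compared array left out, called in 2 of the 6 fits. The interaction was positive in 121 called genes and negative in 14. Of 19 NF-kappa-B genes 10 had a positive called interaction, and 17 adjusted over the list alone (median 1.8, adjusted p = 1.3e-23 with the preset correlation, adjusted p = 0.14 with an estimated correlation, adjusted p = 0.0035 by fry). Of 29 cytokine and chemokine genes 6 did, and 14 adjusted over the list alone with 2 negative (median 1.22, adjusted p = 1.3e-09, adjusted p = 0.28 with an estimated correlation). Cardiac markers had a median interaction of 2.13 with 0 called (adjusted p = 0.0017, adjusted p = 0.65 with an estimated correlation). The count of 135 was 69 without sham replicate 2, 48 without BD replicate 1, 79, 235 and 72 without SEW replicate 1, 2 or 3, and 44 and 38 without BD/SEW replicate 1 or 2. It was 464 with array weights, 24 at an adjusted p under 0.01 and, chosen after seeing the data, 78 with the cardiac covariate and 418 without BD replicate 2, SEW replicate 2 and sham replicate 3.

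**Figure D3:**
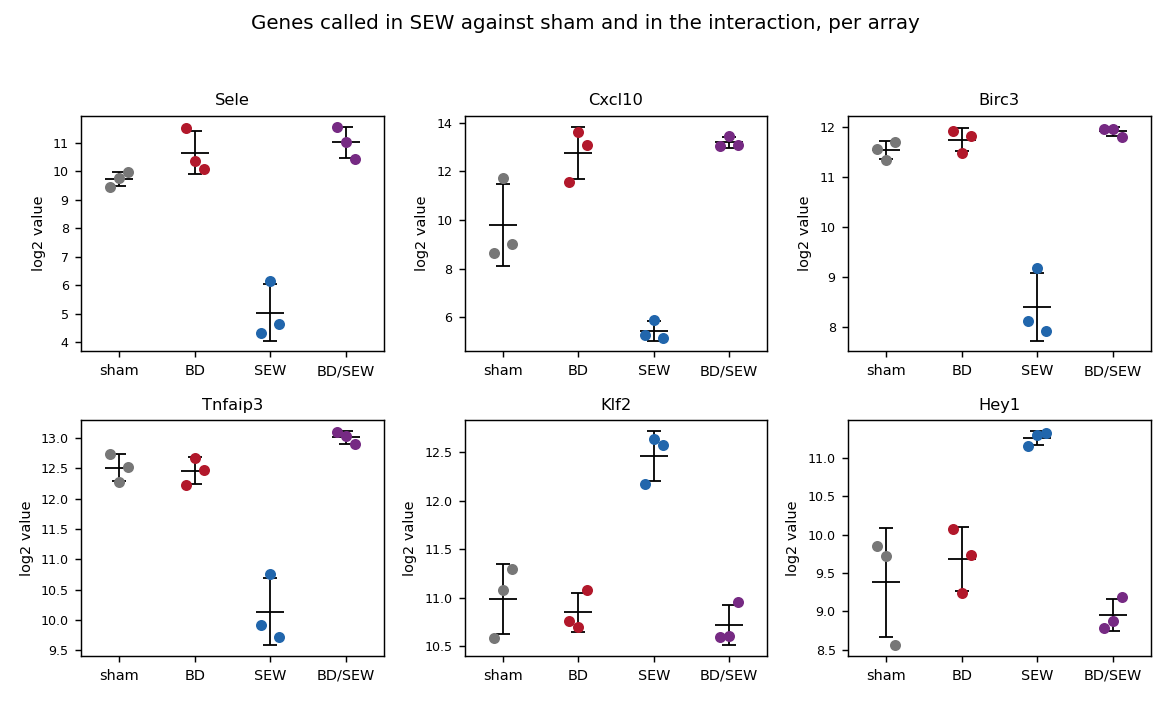
Log2 value (y axis) of 6 genes called in SEW against sham and in the interaction, in each array of the 4 groups (x axis); points are arrays and bars give the mean ± SD of 3 arrays. Sele averages 5.03 in SEW and 9.73 to 11.02 in the other groups, and Klf2 averages 12.46 in SEW and 10.71 to 10.98 in the others.

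The brain-death response without the agonist was set beside that with it. Of the 84 genes called in BD against sham, 77 (91.7%) had the same sign in BD/SEW against SEW, Mycn, Rgs1, Sik1 and Fam222a among them. This share lies below the simulations without an interaction, which gave 95.9% to 97.9%, or 94.6% to 98.2% with shrunk effects. Called in both were 21 genes that rose and 34 that fell, where independent lists would share 1.43 and 2.72, and 2 genes were called in opposite directions. The 2 comparisons use the same variance estimate per gene, which by itself can raise the number called in both, in either direction. The correlation of the fold changes across all genes was 0.359, genes not being independent replicates. It was 0.278 without BD replicate 2, 0.282 without sham replicate 1 and 0.431 without BD replicate 1. In simulations without an interaction it lay between 0.708 and 0.742, or between 0.527 and 0.58 with shrunk effects (chosen after seeing the first result). The slope over the 84 genes was 0.84, inside the range of 0.783 to 0.861 of the first simulations and above the range of 0.678 to 0.786 with shrunk effects. These simulations called a median of 1010 genes in BD against sham, or 476 with shrunk effects, against 84 in the data. Their brain-death effect was the average of the 2 comparisons. It thus carries part of the larger effect in BD/SEW against SEW (1392 calls) into BD against sham. How much of the excess this explains was not tested. The simulated setting differs from the data in this way, which limits what the ranges show.

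The effect of the agonist was then followed over the genes called in BD against sham. Of the 84 genes, 36 (42.9%) moved in BD/SEW against BD opposite to their change in BD against sham, 7 of the 30 raised genes and 29 of the 54 lowered genes. The median change toward sham was -0.0233 log2 units, slightly away from sham. Tnfsf10 was 11.07 ± 0.15 in BD and 11 ± 0.21 in BD/SEW, and Rgs1 was 7.77 ± 0.38 and 7.9 ± 0.1 (log2 mean ± SD, n = 3). Shared BD arrays alone raise this share: in simulations without an agonist effect it lay between 66.5% and 71.3%, or between 67.2% and 76.5% with shrunk effects, with medians of 959 and 276 genes called in place of 84. The share was 62.1% without BD replicate 2 and 73% without BD replicate 3, and 23.1% with the compared arrays only. Chosen after seeing the data, it was 60.7% with the cardiac covariate and 62.7% without BD replicate 2, SEW replicate 2 and sham replicate 3.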

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

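Chosen after the result was seen were the tests of an unoperated SEW group, of heart and fat tissue in BD replicate 2, of blood, platelets and basophils, and the left-out sham arrays beside the place of BD replicate 2. The cardiac covariate was chosen after the data were seen, and the condition on the 25th percentile after the erythroid median of 0.0567, which without it would argue against more blood.

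The brain-death effect differed between animals with and without the agonist, by the test of the interaction, in 121 genes with a positive and 14 with a negative interaction. The NF-kappa-B list mean was 10.51 in sham, 10.74 in BD, 9.33 in SEW and 11.11 in BD/SEW. For cytokines and chemokines it was 9.05, 9.34, 7.99 and 9.9 in the same order. Low values in SEW thus carry much of these positive interactions, while BD/SEW against BD had 2 called genes. The real split gave 135 genes and the highest of the other splits, drawn among the arrays with and among those without brain death, gave 111. Only the real split among 100 was as large. The other splits mix sham with SEW arrays and BD with BD/SEW arrays, which widens the spread wherever these groups differ. Their counts (median 0) are thus low with or without an interaction, so chance was not excluded for the gene count. The labels do not say whether the SEW animals had the sham operation, so the difference is not shown to be an effect of the agonist.

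Positive log2 interactions among named genes were 5.64 for Cxcl11, 5.35 for Il6, 5.32 for Tfpi2, 5.06 for Sele, 4.79 for Cxcl10, 3.78 for Ebi3, 3.6 for Selp, 3.4 for Camp, 3.3 for Birc3, 3.29 for Batf, 3.28 for Csf3 and 3.11 for Mmp9. They were 2.93 for Tnfaip3, 2.62 for Tnfaip2, 2.45 for Slc2a3, 2.11 for Nfkbiz, 2.06 for Slc7a11, 1.92 for Mki67, 1.61 for Fosl2, 1.55 for Hk1, 1.43 for Vcam1, 0.95 for Zfp36 and 0.77 for Stat3. The sizes for Cxcl11, Il6, Tfpi2, Sele and Cxcl10 are uncertain, as their SEW means lie below the lower quartile of the arrays. Negative ones were -2.61 for Hey1, -1.68 for Afap1l1, -1.61 for Klf2, -1.31 for Hoxa5, -1.27 for Palmd, -1.21 for Hspa12b, -1.15 for Hoxb6, -1.09 for Klf10, -1.06 for Zbtb8a and -1.02 for Sh2d3c. Of these 33 genes, 8 passed in every fit with an array left out, namely Birc3, Csf3, Hk1, Sele, Slc2a3, Slc7a11, Tnfaip3 and Vcam1.

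Lists past the preset-correlation test had median interactions of 2.13 (cardiac), 1.8 (NF-kappa-B), 1.22 (cytokines and chemokines), 1.13 (neutrophil), 0.99 (interferon), 0.55 (matrix and acute phase), 0.54 (immediate early), 0.53 (cell cycle), 0.41 (B cell), 0.24 (MHC class II), 0.18 (endothelial activation), 0.08 (hypoxia), -0.18 (alveolar type 1), -0.2 (ribosomal) and -0.33 (endothelial identity). None of the 15 passed with an estimated correlation, where the lowest adjusted p was 0.14. Adjusted within the comparison, the real split gave 16 lists and the highest other split 18, and 7 of the 100 splits gave as many, so chance was not excluded for the list count.

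NF-kappa-B genes were lower in SEW than in sham, while heart transcripts were also lower. With the cardiac marker mean as a covariate the list median was -1.42, against -1.23 without it. It lay between -1.47 and -1.13 with each compared array left out. The spread of the cardiac mean within groups sets this adjustment. Its SD was 2.82 in BD, 0.5 in sham, 0.79 in SEW and 1.11 in BD/SEW. BD replicate 2 (11.38) was in all of these fits, so they do not decide whether heart tissue in the sham pieces was the cause. The called members went from 14 to 5, the mean SE having risen from 0.213 to 0.296. SEW animals without the sham operation may differ in the same way as the agonist's effect (-1.23), and the design cannot separate these, since the labels give no operated SEW group. An effect of the agonist stays open as well.

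Lines from sham (0) to BD/SEW (1) were drawn over called genes, with the cardiac, adipose and airway lists left out. Over 403 genes BD replicate 2 stood at 0.54, nearer to sham than BD replicates 1 and 3 at 0.77 and 0.72. On lines drawn with sham replicate 1, 2 or 3 left out, over 141, 214 and 320 genes, the left-out sham array stood at 0.11, 0.29 and 0.3 and BD replicate 2 at 0.66, 0.77 and 0.59, which for these genes argues against a sham array under a BD label. Over all genes, with no list left out, its mean correlation was 0.985 with the sham arrays and 0.98 with the other BD arrays. Heart and fat tissue in that piece is a candidate explanation, since 17 of 18 cardiac and 10 of 12 adipose markers were more than 1 log2 unit above both other BD arrays. No biological explanation was tested.

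Mcpt8, Mcpt9 and platelet markers were higher in BD/SEW than in BD. More blood in the pieces stays open: erythroid markers had a median of 0.0567 against 0.92 for platelet markers, but only 3 of the 7 lay above the 25th percentile of all genes, the abundant Hbb (-0.14 ± 0.72) and Alas2 (0.27 ± 0.69) having wide errors and Slc4a1 (0.06 ± 0.14) a narrow one far below the platelet median. More platelets in the lung may be a source, since 9 of 9 platelet markers other than Tubb1 and P2ry12 were higher, Pf4 at 10.28 and 11.1. More basophils stay open too, as other basophil markers had a median of 0.28 (SD 0.235 over 5 members), and an effect of the agonist was not separated from either.

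For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05. The real gene count and the highest other were 84 and 16 for BD against sham, 830 and 0 for SEW against sham, 2 and 0 for BD/SEW against BD, 1392 and 0 for BD/SEW against SEW, and 408 and 0 for BD/SEW against sham, so 1 split, the real one, was as large in each. For lists adjusted within a comparison they were 10 and 12 (2 of 10 splits as large), 16 and 15 (1), 11 and 16 (2), 10 and 13 (4), and 11 and 13 (3), in the same order.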

How the results depend on the processing

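The cardiac covariate, the fit without BD replicate 2, SEW replicate 2 and sham replicate 3 (3 arrays left out), and shrunk effects in the simulations were chosen after seeing the data; all other alternatives were chosen before. Except for the 0 calls in BD/SEW against BD with the filters on dim genes, the cause was not tested.

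Gene counts, in the order BD against sham, SEW against sham, BD/SEW against BD, BD/SEW against SEW, BD/SEW against sham and interaction, were 84, 830, 2, 1392, 408 and 135. Those more than 1.5 times away were as follows. With the compared arrays only the counts were 13, 257 and 8 for the first 3 and 685 for BD/SEW against sham. With array weights they were 383, 1556, 5, 2506, 2685 and 464. Over every probe set they were 134 for BD against sham, 4 for BD/SEW against BD and 2198 for BD/SEW against SEW. At 1.5-fold or more they were 512 for SEW against sham and 914 for BD/SEW against SEW. At an adjusted p under 0.01 they were 22, 109, 629, 89 and 24, BD/SEW against BD keeping 2. With either filter on dim genes BD/SEW against BD had 0 calls, Mcpt8 and Mcpt9 being among the genes removed. With the cardiac covariate they were 28 for BD against sham, 24 for SEW against sham, 12 for BD/SEW against sham and 78 for the interaction. With the 3 arrays left out they were 499 for BD against sham, 1160 for BD/SEW against sham and 418 for the interaction. With each array left out the counts ran from 26 to 227, 321 to 554, 1 to 5, 790 to 1360, 91 to 322 and 38 to 235.

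The correlation of brain-death effects (0.359) was 0.429 with the stricter filter on dim genes, 0.278 with the 3 arrays left out and 0.278 to 0.431 with each left out. The share of brain-death genes with opposite signs in BD/SEW against BD and BD against sham (42.9%) was taken over the genes each fit called. It was 23.1% with the compared arrays only, 60.7% with the cardiac covariate, 62.7% with the 3 arrays left out and 38.8% to 73% with each left out. Of 174 list tests 72 passed, 0 with an estimated correlation, 19 with fry, and 64 to 81 with each array left out. The list of cardiac muscle markers in BD/SEW against BD changed sign without BD replicate 2 (adjusted p = 0.65) and with the 3 arrays left out (adjusted p = 0.76), over a range of 1.1e-13 to 0.76. The list of heat shock and chaperone genes in BD/SEW against SEW changed sign without SEW replicate 2 (adjusted p = 0.7) and with the 3 arrays left out (adjusted p = 0.67), over a range of 0.00051 to 0.74.

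With the replicate number as a block the counts were 69, 1018, 3, 1504, 432 and 146, and 71 of the 72 list calls passed. Whether the numbers pair the arrays was not settled. Of 18 same-number pairs 8 had deviations correlated over 0.1 (range -0.19 to 0.38). The median was 0.09 for the same number and -0.04 for different numbers, and 10 of 12 arrays correlated best with their own number. Of 4891 values of named genes over the alternatives chosen before, 3964 kept their side of the threshold, 925 were weaker, 2 stronger and 0 reversed. With the cardiac covariate 130 of 254 values kept their side and 124 were weaker, and with the 3 arrays left out 234 kept it and 20 were weaker. Quantile normalization and median centring kept all 72 list calls, while the cardiac covariate kept 48 and left 24 weaker. Called genes with other probe sets numbered 24 in BD against sham, 245 in SEW against sham and 496 in BD/SEW against SEW. Another probe set passed the same way in 3, 46 and 150 of them and had the opposite sign in 5, 46 and 86. They numbered 127 in BD/SEW against sham and 42 in the interaction, with 21 and 3 passing the same way and 16 and 6 of opposite sign. In BD/SEW against SEW 3 passed the opposite way. The pseudocount alternative was not run, since the values are log2. With all control probe sets absent, signal over background was not measured.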

Other observations

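The platelet and other marker lists below, and their tests, were chosen after the data were seen.

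Platelet markers were higher in BD/SEW than in every other group. Of 11 markers 11 rose against SEW, among them Pf4, the platelet chemokine (1.67 ± 0.26, log2 fold change ± SE, n = 3 per group, adjusted p = 0.0022 by limma), and P2ry12, the platelet ADP receptor (1.21 ± 0.15, adjusted p = 0.00051). Against sham 8 rose, the tubulin gene Tubb1 by 1.87 ± 0.34 (adjusted p = 0.016). Against BD 0 passed over all genes and 11 did adjusted over the list alone (median 0.92, adjusted p = 8.7e-15, adjusted p = 0.12 with an estimated correlation, adjusted p = 0.023 by fry). These tests include Tubb1 and P2ry12, by which the pattern was seen. Without them 9 of 9 members were higher than in BD (median 0.92). The list mean was 9.4, 9.35 and 8.71 in the BD/SEW arrays and 7.32 to 8.43 in the other 9.

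Among 13 basophil markers Mcpt8 rose against each other group, and Hdc, the enzyme that makes histamine, rose by 1.18 ± 0.22 against SEW (n = 3 per group, adjusted p = 0.0056 by limma), where Gata2 fell by 0.69 ± 0.2. In BD/SEW against BD the list median was 0.153 (adjusted p = 0.0033, adjusted p = 0.12 with an estimated correlation). That test includes Mcpt8, the 1 member called in this comparison and already seen to rise. The 8 mast cell markers had a median of 0.0317 there with 0 called (adjusted p = 0.45).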
